A study of Mus musculus with 6 samples.

How the data were processed

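Messenger RNA of mouse hearts was measured in 6 libraries, 2 in each of 3 groups (control, CFZ and CFZ_EA). Per the labels' protocols, RNA with an integrity number above 7 was selected on oligo(dT) in 2 rounds, a strand-marking dUTP kit was used, and libraries were sequenced in pairs of 150 base reads on an Illumina NovaSeq. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d and the GRCm38 build, without a role or order for each. The annotation release, the filters and whether counting used strand are not given in the sources used here. Per the file headers, the deposited table holds FPKM values, made by the authors, in 1 column per library. Per the file headers it also holds a count column per library, and these deposited values were treated as estimated counts and rounded to whole numbers. Between 42.2% and 43.3% of the counts from 1 to 20 were multiples of 4, against 25% by chance, so a count may stand for less than a read, and counting error is then larger than the counts show. The table lists 26835 genes, whose IDs all matched GENCODE M21 on GRCm38, 24273 with the same start and end.

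Estimated counts totalled 50013990 to 75742448 per library, and 3 counts, the floor used for a count of 0, corresponded to 0.0396 to 0.0600 CPM. Intervals and floors cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules. Mitochondrial genes took 14.8% of the counts in control replicate 2 and up to 21.3% in CFZ_EA replicate 2. No pair of libraries held identical values, and Pearson's r between libraries ran from 0.937 to 0.977 across the tested genes. The labels do not say whether the replicates of a group came from separate mice, so p-values measure only the spread between these samples, which may be technical.

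The design fixed before the data were examined assumed that only FPKM values would be present and named limma on log2(scaled FPKM + 1) as the test. Because counts were present, edgeR's quasi-likelihood test on the counts was used, and the limma test became an alternative. Genes with a mean FPKM of at least 1 over the 6 libraries were tested, 10329 in all, 9272 of them protein coding. Counts were scaled with TMM factors (0.955 to 1.08), and 1 model with group as its only term was fitted to all 6 libraries, leaving 3 residual degrees of freedom. Benjamini-Hochberg adjusted p-values under 0.05 were called. An exact two-sided test of 2 against 2 libraries cannot go below p = 0.333, so none was used. Log2 fold changes carry standard errors from the same fit, and FPKM values are means with standard deviations. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and Python 3.11.15 were used.

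Of 42 gene lists fixed before the data were examined, 36 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. The other 6 (neutrophil, T and NK cell, B and plasma cell, Schwann and neuronal, skeletal muscle and lung epithelial markers) had fewer tested members and were left out. Camera compares a list with all other genes, and fry tests whether its members move one way on balance. No camera call held with an estimated correlation in any comparison. Genes were named by a rule fixed in advance: per comparison the 8 largest changes in each direction among called genes whose groups do not overlap, filled up with the smallest unadjusted p, up to 4 members of each called list, and Psmb5, Nppa, Nppb, Myh6 and Myh7. Gene models without a proper symbol were left out of the first part. The text names a part of the genes this rule gives, and 1 gene was taken out of them and is not reported here.

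The same steps were tested on simulated counts for 10329 genes. For CFZ against control 20.9% of 2-fold, 97.0% of 4-fold and 98.5% of 8-fold changes were recovered with 8 false calls. For CFZ_EA against CFZ the shares were 31.3%, 94.0% and 97.0% with 15 false calls, and for CFZ_EA against control they were 23.9%, 92.5% and 98.5% with 8 false calls. Genes were drawn independently, changes were placed only in genes above a minimum expected count, and no library was outlying. An uncalled gene can therefore differ by more than 4-fold: Timp1, with a log2 fold change of -4.68 for CFZ against control, was not called. Alternatives covered the filter, the scaling, the test, the groups in the fit, the replicate number as a block and each library left out in turn. Added after seeing the data were DESeq2, other scaling factors, counts divided by 4, overlapping gene models summed, the atrial marker level as a covariate, and the fit without control replicate 2 and CFZ_EA replicate 2.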

Results

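RNA sequencing was carried out on hearts of C57BL/6 mice aged 7 to 8 weeks and weighing about 20 g, to ask how carfilzomib alters cardiac gene expression and how electroacupuncture alters it in carfilzomib-treated mice. Carfilzomib is an irreversible inhibitor of the proteasome that is used against multiple myeloma and can harm the heart. Electroacupuncture passes a current through needles, here placed at the acupoint PC6 on the forelimb. The data comprised 3 groups with 2 libraries each. Control mice received 10% DMSO by intraperitoneal injection, CFZ mice received carfilzomib at 8 mg/kg, and CFZ_EA mice received carfilzomib at 8 mg/kg and electroacupuncture. The labels list days 0, 2, 4 and 6 for every library without tying a day to an event. Estimated counts totalled 57360755 and 50013990 in the control libraries, 65144234 and 63430597 in CFZ, and 65578510 and 75742448 in CFZ_EA.

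In CFZ hearts, gene lists of protein folding in the endoplasmic reticulum, the interferon response, the extracellular matrix, the epicardium and the atria were lower than in control, and the list of oxidative phosphorylation was higher. Manf, a secreted protein induced by endoplasmic reticulum stress (chromosome 9, 106838312 to 106891915, GRCm38), measured 29.0 ± 7.35 FPKM in control and 12.1 ± 0.948 FPKM in CFZ (SD, n = 2 each). Lifr, the receptor of leukaemia inhibitory factor (chromosome 15, 7090614 to 7197489), measured 0.666 ± 0.0980 FPKM in control and 1.82 ± 0.138 FPKM in CFZ. Neither gene passed over all genes: the log2 fold changes were -1.20 ± 0.15 (SE) and 1.51 ± 0.16, with adjusted p = 0.439 and 0.185 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 36 gene lists, camera with a preset correlation called 8 higher and 12 lower in CFZ. With an estimated correlation it called 0, and fry called 0 after adjustment and 6 at an unadjusted p under 0.05.

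The unfolded protein response list, which holds chaperones and folding enzymes of the endoplasmic reticulum, had 20 of 21 members lower in CFZ and a median log2 fold change of -0.47 (camera adjusted p = 1.5e-14, and adjusted p = 0.304 with an estimated correlation). Adjusted over the list alone 12 members passed, and 0 passed over all genes. The chaperone cofactor Sdf2l1 had a log2 fold change of -1.57 ± 0.29, and the disulfide isomerases Pdia4 and Pdia3 had -1.12 ± 0.22 and -0.76 ± 0.17. Integrated stress response genes, which include targets of the transcription factor ATF4, had 12 of 13 members lower and a median of -0.36 (adjusted p = 0.553 with an estimated correlation). Nupr1, a stress-induced chromatin protein, had -1.73 ± 0.60, and 0 members of that list passed over all genes or adjusted over the list alone. The integrated stress median was -0.11 without control replicate 2 and -0.18 without CFZ replicate 1, where the list did not pass, and -0.56 without control replicate 1. Nupr1 had -0.61 without control replicate 2.

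Interferon response genes were lower in CFZ in 18 of 18 cases, with a median of -0.72 (adjusted p = 0.304 with an estimated correlation). The guanylate-binding proteins Gbp2 and Gbp3 had log2 fold changes of -0.84 ± 0.17 and -1.11 ± 0.24, 2 members passed adjusted over the list alone and 0 over all genes, and the median was -0.24 without control replicate 2. Antigen presentation and immunoproteasome genes had 10 of 12 members lower and a median of -0.43 (adjusted p = 0.381 with an estimated correlation), with 4 passing adjusted over the list alone and 0 over all genes. B2m, the light chain of class I molecules, measured 343 ± 11.6 FPKM in control and 242 ± 14.5 FPKM in CFZ. That list did not pass without control replicate 1 (median -0.37), and its median was -0.23 without CFZ replicate 1. Macrophage markers were lower in 13 of 13 cases (median -0.99, and adjusted p = 0.456 with an estimated correlation), with Csf1r, the receptor of colony-stimulating factor 1, at -0.97 ± 0.29 and the lysozyme gene Lyz2 at -1.39 ± 0.44. Their median was -0.26 without control replicate 2, where Csf1r and Lyz2 had -0.45 and -0.49, and -1.52 without control replicate 1. Genes of cytokines and NF-kB targets had 14 of 14 members lower and a median of -0.96 (adjusted p = 0.553 with an estimated correlation), and without control replicate 2 the median was 0.0026 and the list did not pass. In the macrophage and cytokine lists 0 members passed over all genes and 0 adjusted over the list alone.

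The extracellular matrix list was lower in CFZ than in control, and its genes also differed between the control libraries. Of 27 extracellular matrix genes 26 were lower in CFZ, with a median log2 fold change of -1.54 (camera adjusted p = 3.8e-20, and adjusted p = 0.364 with an estimated correlation), and 21 passed adjusted over the list alone against 0 over all genes. Postn, a matricellular protein of activated fibroblasts, had -4.15 ± 0.99, and Timp1, an inhibitor of matrix metalloproteinases, had -4.68 ± 1.21. Col1a1, a chain of type I collagen, measured 21.3 FPKM in control replicate 1 and 287 FPKM in control replicate 2, and Timp1 measured 6.49 and 105 FPKM. Without control replicate 2 the median of the matrix list was -0.45 and the list still passed (camera adjusted p = 5.0e-13), and Postn and Timp1 had -1.92 and -1.70. Fibroblast markers were lower in 13 of 13 cases (median -0.98, and adjusted p = 0.346 with an estimated correlation), with Dpt and Lum, collagen-binding matrix proteins, at -1.25 ± 0.37 and -1.39 ± 0.39. Among them 11 passed adjusted over the list alone and 0 over all genes, and the median was -0.51 without control replicate 2, where Dpt and Lum had -0.51 and -0.68.

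Epicardial and mesothelial markers had 5 of 5 members lower in CFZ and a median log2 fold change of -3.68 (adjusted p = 0.304 with an estimated correlation). Krt19, an epithelial keratin, measured 8.57 ± 5.78 FPKM in control and 0.394 ± 0.128 FPKM in CFZ. Erythroid markers had 5 of 5 members lower and a median of -0.77 (adjusted p = 0.346 with an estimated correlation), with Alas2, the erythroid enzyme of haem synthesis, at -0.84 ± 0.19. The globin genes Hba-a1 and Hba-a2 are near-identical and can share reads, so their separate values are uncertain. In both lists all 5 members passed adjusted over the list alone and 0 over all genes. The labels do not say which part of the heart was taken, and the share of epicardial tissue or blood in the pieces was not tested.

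Atrial cardiomyocyte markers had 9 of 10 members lower in CFZ and a median of -3.15 (adjusted p = 0.381 with an estimated correlation), with 6 passing adjusted over the list alone and 0 over all genes. Nppa, the atrial natriuretic peptide gene (chromosome 4, 148000722 to 148002079), measured 1485 ± 568 FPKM in control and 210 ± 33.1 FPKM in CFZ, and Myl7, the atrial regulatory light chain, measured 557 ± 220 and 44.5 ± 46.7 FPKM. The atrial median was -1.80 without control replicate 1, and the log2 fold change of Myl7 was -3.64 with all libraries and -5.51 without CFZ replicate 1. The share of atrial tissue in the pieces, which the labels do not give, was not tested for this comparison. In a second set of atrial genes, Sbk2 and Gja5 had -1.45 and -0.92, and Kcnj5 and Chrm2 had -0.034 and -0.079. The cardiac stress and fetal gene list, which shares Nppa and Myl4 with the atrial list, had 16 of 18 members lower and a median of -0.44 (adjusted p = 0.304 with an estimated correlation), with 3 passing adjusted over the list alone and 0 over all genes. Fhl1, a LIM-domain protein of the sarcomere, had -0.76 ± 0.18, and the nicotinamide riboside kinase Nmrk2 had -1.77 ± 0.45. The stress median was -0.23 without control replicate 1, -0.19 without CFZ replicate 1 and -0.80 without CFZ replicate 2.

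Gene lists of energy metabolism, contraction and the proteasome were higher in CFZ with medians nearer 0, and of their genes 0 passed over all genes. All 42 nuclear genes of oxidative phosphorylation were higher in CFZ, with a median log2 fold change of 0.24 (camera adjusted p = 4.5e-09, and adjusted p = 0.553 with an estimated correlation), and the median was 0.10 without control replicate 2 and 0.37 without control replicate 1. The respiratory chain genes Ndufa4 and Cycs had 0.28 ± 0.11 and 0.37 ± 0.17, and Cycs had 0.61 without control replicate 1 and 0.16 without control replicate 2. Fatty acid oxidation genes were higher in 29 of 31 cases (median 0.20, and adjusted p = 0.588 with an estimated correlation), and sarcomere genes in 18 of 22 (median 0.17, and adjusted p = 0.553 with an estimated correlation), with cardiac troponin I, Tnni3, at 2288 ± 154 FPKM in control and 2948 ± 31.0 FPKM in CFZ. Proteasome subunits were higher in 31 of 34 cases, with a median of 0.11 (adjusted p = 0.627 with an estimated correlation). Psmb5, the catalytic subunit that carfilzomib binds, measured 131 ± 7.24 FPKM in control, 138 ± 10.0 FPKM in CFZ and 128 ± 0.0839 FPKM in CFZ_EA, and its log2 fold change between CFZ and control ran from 0.0039 to 0.25 with 1 library left out. Without control replicate 2 the fatty acid, sarcomere and proteasome medians were 0.044, 0.058 and 0.071, and none of these 3 lists passed. Without CFZ replicate 2 the sarcomere and proteasome lists did not pass, at 0.098 and 0.024, and the proteasome median was 0.17 without CFZ replicate 1. Without control replicate 1 the fatty acid and sarcomere medians were 0.37 and 0.32.

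Glycolysis genes were higher in 19 of 22 cases (median 0.14, and adjusted p = 0.346 with an estimated correlation), with the hexokinase Hk1 at 0.52 ± 0.12, and the median was 0.22 without control replicate 1 and 0.089 without CFZ replicate 2. Calcium handling genes were higher in 18 of 23 cases (median 0.12, and adjusted p = 0.553 with an estimated correlation), with the sodium-calcium exchanger Slc8a1 at 0.60 ± 0.18. The AMPK, mTOR and insulin list had 15 of 19 members higher (median 0.12, and adjusted p = 0.482 with an estimated correlation). Circadian clock genes were higher as a list, with 10 of 15 members higher and a median of 0.24 (adjusted p = 0.346 with an estimated correlation), but its members went both ways. Dbp and Nr1d1, clock output and repressor genes, had 0.99 ± 0.23 and 0.73 ± 0.17, whereas the activators Arntl and Npas2 had -0.70 ± 0.22 and -0.68 ± 0.23, and both had -0.44 without CFZ replicate 2. Without control replicate 2 the calcium, AMPK and clock medians were 0.030, 0.012 and 0.12, without CFZ replicate 1 they were 0.11, 0.076 and 0.38, and none of the 3 lists passed in either case. Medians moved by over 1.5 times without loss of the call for the calcium and clock lists without control replicate 1 (0.27 and 0.36) and for the calcium and AMPK lists without CFZ replicate 2 (0.23 and 0.19). In the clock list 2 members passed adjusted over the list alone, in the other 7 metabolic, contractile and proteasome lists 0 did, and 0 passed over all genes.

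Over 10329 genes, edgeR's quasi-likelihood test called 0 genes higher and 3 lower in CFZ than in control, against 196 higher and 613 lower at an unadjusted p under 0.05, where chance gives 516 in all. DESeq2 called 27 higher and 111 lower. The 3 called genes were Sept2, a septin (ENSMUSG00000116048, chromosome 1, 93478993 to 93509733), Mir8114, a microRNA gene (ENSMUSG00000099227, chromosome 1, 153899926 to 153900036), and 1500015O10Rik (ENSMUSG00000026051, chromosome 1, 43730602 to 43742578), which was chosen after its values were seen. Sept2 had 5353 counts over the control libraries and 0 over the CFZ libraries, at least 1030-fold lower against a floor of 3 counts per library (edgeR adjusted p = 0.00382). Mir8114 had 736 and 2 counts, a ratio of 425 with a 95% counting interval of 117 to 3513 (edgeR adjusted p = 0.00327). If a count stands for less than a read, the bound for Sept2 is too high and the interval for Mir8114 too narrow. The gene 1500015O10Rik measured 5.13 ± 1.71 FPKM in control and 0.177 ± 0.00430 FPKM in CFZ, and its log2 fold change was -4.68 ± 0.36 (edgeR adjusted p = 0.0407). The Sept2 and Mir8114 models overlap another gene model on the same strand, a second Sept2 model and Glul, so their values are uncertain. Summed with those models the log2 fold changes were -0.06 and 0.17, and edgeR then called 0 genes over all loci. None of the 3 called genes passed without CFZ replicate 1. Many more genes passed without control replicate 1, but control was then replicate 2 alone. Control replicate 2 lay at 48.0 on the first principal component of log2 CPM, which held 37.2% of the variance. The other libraries lay from -22.1 to 0.37. Without CFZ replicate 1 the adjusted p of Sept2 and Mir8114 were 0.0625 and 0.155, while their fitted log2 fold changes, which depend on the prior count, were -14.56 and -8.49 against -14.58 and -8.55 with all libraries. Mir8114 did not pass without CFZ replicate 2 (fitted log2 fold change -8.61, edgeR adjusted p = 0.120), and 1500015O10Rik did not pass without control replicate 2, CFZ_EA replicate 1 or CFZ_EA replicate 2. Nor did it pass with limma on log2(scaled FPKM + 1), with library totals only or in the fit of the 2 compared groups, where Sept2 and Mir8114 were the 2 genes called lower.

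Among genes with the smallest unadjusted p, Nsun4, a methyltransferase of mitochondrial ribosomal RNA, had a log2 fold change of 1.47 ± 0.20, Jmjd4 had 1.43 ± 0.21, Mllt6 had 1.02 ± 0.15 and the kinase Riok3 had 0.79 ± 0.12 in CFZ against control. Comp, a cartilage matrix protein, had -2.33 ± 0.35, Sost, a secreted inhibitor of Wnt signalling, had -1.98 ± 0.32, and Angptl7 had -2.26 ± 0.35. None of these 7 genes passed over all genes. Nppb, the B-type natriuretic peptide gene, and the myosin heavy chain genes Myh6 and Myh7 had log2 fold changes of -0.21 ± 0.65, 0.11 ± 0.30 and 0.09 ± 0.27, and with 1 library left out they ran from -1.40 to 0.63, from 0.0064 to 0.23 and from 0.020 to 0.16.

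**Figure D1:**
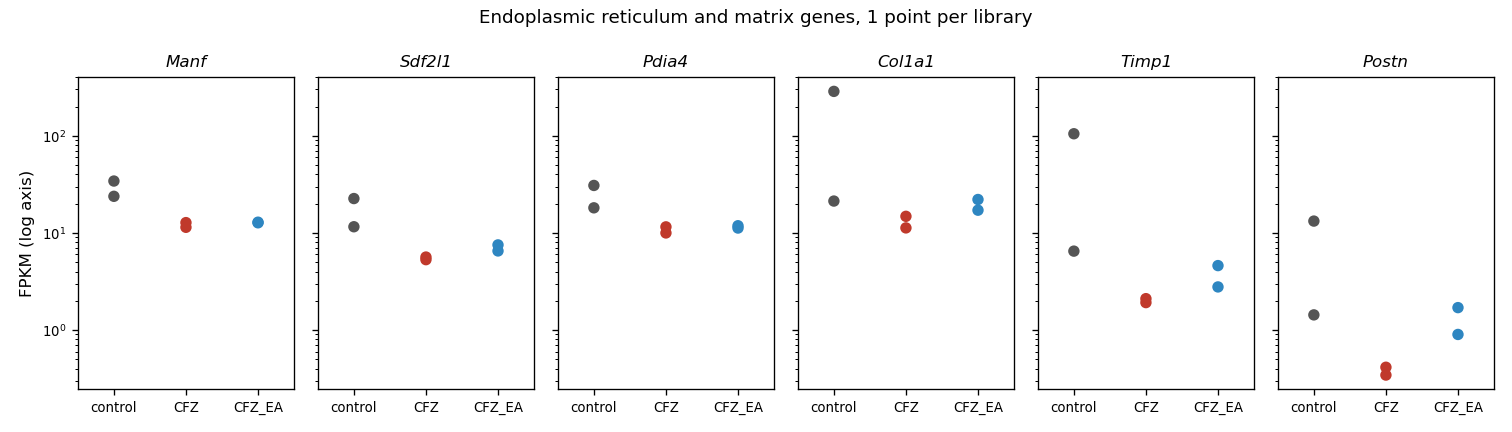
FPKM (log axis) of 3 endoplasmic reticulum genes (Manf, Sdf2l1, Pdia4) and 3 matrix genes (Col1a1, Timp1, Postn) in control, CFZ and CFZ_EA hearts, with 1 point per library and 2 libraries per group. The control points of Col1a1 lie at 21.3 and 287 FPKM, and Manf averaged 29.0 FPKM in control, 12.1 FPKM in CFZ and 12.8 FPKM in CFZ_EA.

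In CFZ_EA hearts, the lists of atrial, fibroblast, epicardial, matrix and mitochondrially encoded genes were higher than in CFZ, while the lists of nuclear oxidative phosphorylation genes and endothelial markers were lower. Nppa measured 210 ± 33.1 FPKM in CFZ and 2264 ± 2289 FPKM in CFZ_EA (SD, n = 2 each), with 646 FPKM in CFZ_EA replicate 1 and 3882 FPKM in replicate 2. Atrial markers had 10 of 10 members higher and a median log2 fold change of 3.71 (camera adjusted p = 1.5e-19, and adjusted p = 0.860 with an estimated correlation). Adjusted over the list alone 7 passed, and 0 passed over all genes. Myl7 had a log2 fold change of 4.24 ± 1.18, the secreted glycoprotein gene Dkk3 had 3.97 ± 0.85, and the lipid transfer gene Stard10 measured 7.55 ± 0.339 FPKM in CFZ and 21.2 ± 10.9 FPKM in CFZ_EA. Without CFZ_EA replicate 2 the atrial median was 1.22, Myl7 and Dkk3 had 2.47 and 2.59, and Nppa and Stard10 had 1.62 and 0.83. Bmp10, a growth factor gene of the right atrium that was chosen after its values were seen, measured 0.0117 and 55.7 FPKM in the CFZ_EA libraries and 22.6 and 0.167 FPKM in control.

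**Figure D2:**
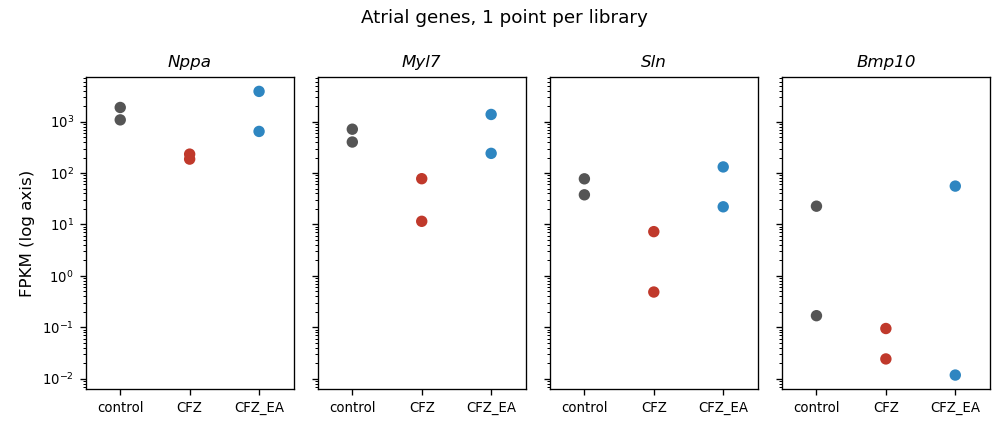
FPKM (log axis) of the atrial genes Nppa, Myl7, Sln and Bmp10 in control, CFZ and CFZ_EA hearts, with 1 point per library and 2 libraries per group. The CFZ_EA points of Nppa lie at 646 and 3882 FPKM and those of Bmp10 at 0.0117 and 55.7 FPKM.

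The cardiac stress and fetal gene list had 15 of 18 members higher in CFZ_EA than in CFZ and a median of 0.40 (adjusted p = 0.774 with an estimated correlation). Its members include the atrial genes Nppa and Myl4, and Ccn2, a matricellular growth factor, had 0.90 ± 0.32. Nppb measured 158 ± 120 FPKM in CFZ and 217 ± 39.2 FPKM in CFZ_EA, Myh7, the fetal myosin heavy chain, 62.1 ± 0.599 and 93.3 ± 38.9 FPKM, and Myh6, the adult heavy chain, 3392 ± 42.5 and 3489 ± 120 FPKM. The log2 fold change of Nppb was 0.44 ± 0.65 and turned to -0.20 without CFZ replicate 1, with 1.63 without CFZ replicate 2, and that of Myh7 was 0.59 ± 0.27, with 0.12 without CFZ_EA replicate 1 and 0.95 without CFZ_EA replicate 2. The stress median was 0.18 without CFZ replicate 1, 0.69 without CFZ replicate 2 and 0.25 without CFZ_EA replicate 1. Fibroblast markers had 12 of 13 members higher (median 0.41, and adjusted p = 0.949 with an estimated correlation), with Gsn, an actin-severing protein, at 0.52 ± 0.13 and Mgp, matrix Gla protein, at 0.63 ± 0.20. Epicardial markers had 5 of 5 higher (median 1.48, and adjusted p = 0.949 with an estimated correlation), and matrix genes had 24 of 27 higher (median 0.35, and adjusted p = 0.991 with an estimated correlation). Without CFZ_EA replicate 2 the epicardial and matrix medians were 0.60 and 0.20 and neither list passed, and the matrix list did not pass without CFZ replicate 2 (0.23).

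Mitochondrially encoded genes had 10 of 13 members higher in CFZ_EA than in CFZ and a median of 0.34 (adjusted p = 0.991 with an estimated correlation), with mt-Nd5, a subunit of complex I, at 0.55 ± 0.34, and at 0.33 without CFZ_EA replicate 2. Nuclear copies of mitochondrial genes took 4.34% to 6.10% of each library's counts, so these values are uncertain. The mitochondrial list did not pass without CFZ replicate 1 (0.15) or without CFZ_EA replicate 2 (0.053), and its median was 0.53 without CFZ replicate 2 and 0.57 without CFZ_EA replicate 1. With the atrial marker level as a covariate, a setting chosen after the data were seen, the direction turned: the mitochondrial median was -0.24 (camera adjusted p = 0.169) and mt-Nd5 had -0.0052. That covariate was the median of the atrial list in these same libraries, and the list itself differed between the groups (median 3.71). The turned direction thus cannot separate the atrial level from the treatment. The epicardial, fatty acid and NRF2 lists did not pass with that covariate either. Nuclear genes of oxidative phosphorylation were lower in 40 of 42 cases (median -0.13, and adjusted p = 0.991 with an estimated correlation), with Ndufb5 at -0.49 ± 0.12. Endothelial markers were lower in 12 of 14 cases (median -0.16, and adjusted p = 0.949 with an estimated correlation), with the fatty acid carrier Fabp4 at -0.60 ± 0.20, and at -0.28 without CFZ replicate 2. Fatty acid oxidation genes were lower in 26 of 31 cases (median -0.09, and adjusted p = 0.991 with an estimated correlation) and NRF2 targets in 17 of 21 (median -0.08, and adjusted p = 0.991 with an estimated correlation), with the glutathione transferase Gstm2 at -0.39 ± 0.12. Without CFZ replicate 2 none of these 4 lists passed, with medians of -0.049, -0.11, -0.059 and -0.033 in the order given. The endothelial and NRF2 lists did not pass without CFZ_EA replicate 1 (-0.12 and -0.15), nor did the NRF2 and fatty acid lists without CFZ_EA replicate 2 (-0.18 and 0.020). Without CFZ replicate 1 the oxidative phosphorylation and NRF2 medians were -0.21 and -0.16, and without CFZ_EA replicate 1 the fatty acid median was -0.21. In the 9 passing lists other than the atrial list, 0 members passed over all genes and 0 adjusted over the list alone.

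Camera called 6 lists higher and 4 lower in CFZ_EA than in CFZ, 4 and 1 with quantile-normalised FPKM, 5 and 0 without CFZ replicate 2, and 4 and 2 without CFZ_EA replicate 2. With an estimated correlation it called 0, and fry called 0 after adjustment and 1 at an unadjusted p under 0.05. The unfolded protein response had a median of 0.09 (camera adjusted p = 0.17) and proteasome subunits had -0.09 (camera adjusted p = 0.088). Of single genes, edgeR's quasi-likelihood test called 2 higher and 0 lower, against 207 higher and 114 lower at an unadjusted p under 0.05, 321 in all where chance gives 516, and DESeq2 called 38 higher and 17 lower. The called genes were Sept2, at least 1093-fold higher against the floor of 3 counts per library, and Mir8114, with a ratio of 382 (95% counting interval 105 to 3159), both with edgeR adjusted p = 0.00369. Here too the bound is too high and the interval too narrow if a count stands for less than a read. Summed with their overlapping models the log2 fold changes were 0.07 and -0.22, and edgeR then called 0 genes. The count of called genes was also 0 without CFZ replicate 1, where Sept2 and Mir8114 had adjusted p = 0.0606 and 0.161 and fitted log2 fold changes of 14.64 and 8.35 against 14.66 and 8.41 with all libraries, and it was 4 without control replicate 1, without control replicate 2 and without CFZ replicate 2. Mir8114 did not pass without CFZ replicate 2 (fitted log2 fold change 8.48, edgeR adjusted p = 0.104).

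Other genes with a small unadjusted p did not pass. Rai1, a transcriptional regulator, measured 1.24 ± 0.105 FPKM in CFZ and 2.89 ± 0.306 FPKM in CFZ_EA (edgeR adjusted p = 0.403). Kidins220, a scaffold of neurotrophin receptors, measured 1.52 ± 0.0667 and 3.69 ± 0.376 FPKM (edgeR adjusted p = 0.422). Snx3, an endosomal sorting nexin, measured 76.7 ± 0.551 and 39.6 ± 5.34 FPKM (edgeR adjusted p = 0.403), and Nutf2, an import factor of the GTPase Ran, measured 14.3 ± 0.838 and 24.2 ± 1.52 FPKM (edgeR adjusted p = 0.563). Scamp4, a secretory carrier membrane protein, had a log2 fold change of 1.93 ± 0.25, and 1.18 when summed with its overlapping models. Sost had 2.21 ± 0.32 and Clcn6, a chloride transporter of endosomes, had -1.40 ± 0.24.

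In CFZ_EA hearts, gene lists of the endoplasmic reticulum, interferon, macrophages, red cells and the epicardium were lower than in control, and the sarcomere list was higher. Manf measured 29.0 ± 7.35 FPKM in control and 12.8 ± 0.131 FPKM in CFZ_EA (SD, n = 2 each). The unfolded protein response list had 17 of 21 members lower and a median log2 fold change of -0.47 (camera adjusted p = 6.1e-13, and adjusted p = 0.413 with an estimated correlation), with 8 passing adjusted over the list alone and 0 over all genes. Hyou1, a chaperone of the endoplasmic reticulum, had -0.84 ± 0.17, Sdf2l1 had -1.20 ± 0.29, and Pdia4 measured 24.5 ± 8.97 FPKM in control and 11.5 ± 0.443 FPKM in CFZ_EA. Sdf2l1 and Pdia4 had log2 fold changes of -0.72 and -0.65 without control replicate 2. The atrial markers had a median of 0.52 and did not pass (camera adjusted p = 0.11).

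Interferon genes were lower in CFZ_EA than in control in 18 of 18 cases (median -0.56, and adjusted p = 0.413 with an estimated correlation), with the interferon regulatory factor Irf7 at -1.11 ± 0.40, and without control replicate 2 the median and Irf7 were both at -0.37. Macrophage markers were lower in 13 of 13 cases (median -1.05, and adjusted p = 0.601 with an estimated correlation), with the protease gene Ctss at -1.33 ± 0.46, and without control replicate 2 the median was -0.25 and Ctss had -0.40. Erythroid markers were lower in 5 of 5 cases (median -0.77, and adjusted p = 0.480 with an estimated correlation), and so were epicardial markers (median -2.20, and adjusted p = 0.413 with an estimated correlation). Msln, mesothelin, had -2.19 ± 0.52, and without control replicate 2 the epicardial median was -1.43 and Msln had -1.29. All 5 erythroid and all 5 epicardial members passed adjusted over the list alone, 0 interferon and 0 macrophage members did, and 0 passed over all genes. Antigen presentation and immunoproteasome genes had 9 of 12 members lower (median -0.26, and adjusted p = 0.601 with an estimated correlation), and the list did not pass without control replicate 1 (-0.15) or CFZ_EA replicate 2 (-0.14).

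The remaining lists that were lower in CFZ_EA than in control did not pass without control replicate 2. Matrix genes were lower in 26 of 27 cases (median -1.24, and adjusted p = 0.601 with an estimated correlation), with Sparc, a collagen-binding glycoprotein, at -1.40 ± 0.43, and fibroblast markers in 12 of 13 (median -0.68, and adjusted p = 0.601 with an estimated correlation), with Col1a1 at -2.85 ± 1.02. Cytokine genes were lower in 13 of 14 cases (median -0.53, and adjusted p = 0.601 with an estimated correlation), with the chemokine Ccl2 at -1.77 ± 0.79, and cell cycle genes in 5 of 6 (median -0.69, and adjusted p = 0.601 with an estimated correlation), with the replication gene Mcm6 at -0.79 ± 0.35. The integrated stress response list had 12 of 13 lower (median -0.19, and adjusted p = 0.603 with an estimated correlation), with asparagine synthetase, Asns, at -0.83 ± 0.37. Without control replicate 2 these 5 medians were -0.14, -0.065, 0.063, -0.063 and -0.043 in the order given, and Sparc, Col1a1, Ccl2, Mcm6 and Asns had -0.53, -0.12, 0.088, -0.17 and -0.24. Without control replicate 1 the fibroblast, cytokine, cell cycle and integrated stress medians were -1.13, -0.90, -1.12 and -0.43, and Mcm6 had -1.22. The cell cycle and integrated stress lists also did not pass without CFZ_EA replicate 1 (-0.54 and -0.16), and the integrated stress median was -0.28 without CFZ_EA replicate 2. In these 5 lists and the antigen presentation list, 0 members passed over all genes and 0 adjusted over the list alone.

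Sarcomere genes were higher in CFZ_EA than in control in 21 of 22 cases (median 0.19, and adjusted p = 0.601 with an estimated correlation), with Cmya5, a protein of the costamere, at 0.35 ± 0.12. Calcium handling genes were higher in 19 of 23 cases (median 0.18, and adjusted p = 0.601 with an estimated correlation), with the potassium channel partner Kcnip2 at 0.58 ± 0.19 and connexin 43, Gja1, at -0.60 ± 0.20. AMPK, mTOR and insulin genes were higher in 16 of 19 cases (median 0.14, and adjusted p = 0.601 with an estimated correlation), and clock genes in 11 of 15 (median 0.17, and adjusted p = 0.598 with an estimated correlation), with Nr1d1 at 0.77 ± 0.17. Mitochondrially encoded genes were higher in 13 of 13 cases (median 0.27, and adjusted p = 0.661 with an estimated correlation), nuclear oxidative phosphorylation genes in 39 of 42 (median 0.11, and adjusted p = 0.715 with an estimated correlation) and fatty acid oxidation genes in 28 of 31 (median 0.11, and adjusted p = 0.715 with an estimated correlation). Without control replicate 2 none of these 7 lists passed, with medians of 0.059, 0.015, 0.093, 0.064, -0.092, -0.025 and -0.056 in the order given. Without control replicate 2 and CFZ_EA replicate 2 together, a setting chosen after the data were seen, the mitochondrial list passed in the opposite direction (median -0.43, camera adjusted p = 5.9e-05). In the 7 lists 0 members passed over all genes and 0 adjusted over the list alone.

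Other single libraries also moved these 7 lists. Without control replicate 1 the sarcomere, calcium, clock, mitochondrial, oxidative phosphorylation and fatty acid medians were 0.34, 0.27, 0.29, 0.84, 0.25 and 0.35. Without CFZ_EA replicate 1 the AMPK, oxidative phosphorylation and fatty acid lists did not pass, at 0.10, 0.085 and -0.029, and the calcium and mitochondrial medians were 0.12 and 0.50. Without CFZ_EA replicate 2 the AMPK, clock and mitochondrial lists did not pass, at 0.14, 0.12 and 0.0017, and the fatty acid median was 0.25.

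Camera called 7 lists higher and 11 lower in CFZ_EA than in control, 3 and 12 with quantile-normalised FPKM, and 1 and 6 without control replicate 2. With an estimated correlation it called 0, and fry called 0 after adjustment and 2 at an unadjusted p under 0.05. Of single genes, edgeR's quasi-likelihood test called 0 higher and 0 lower, with 149 higher and 384 lower at an unadjusted p under 0.05, 533 in all where chance gives 516, and a smallest adjusted p of 0.464. DESeq2 called 26 higher and 25 lower. Lifr measured 1.96 ± 0.233 FPKM in CFZ_EA against 0.666 ± 0.0980 FPKM in control, and Riok3 3.05 ± 0.0910 against 1.62 ± 0.117 FPKM. Nutf2 had a log2 fold change of 1.03 ± 0.12, Kidins220 had 1.24 ± 0.18, and Anp32e, a histone chaperone, had -0.74 ± 0.14, and Snx3 measured 83.0 ± 3.40 FPKM in control and 39.6 ± 5.34 FPKM in CFZ_EA. Many more genes passed without control replicate 1, where control was replicate 2 alone, than with all libraries or without control replicate 2.

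**Figure D3:**
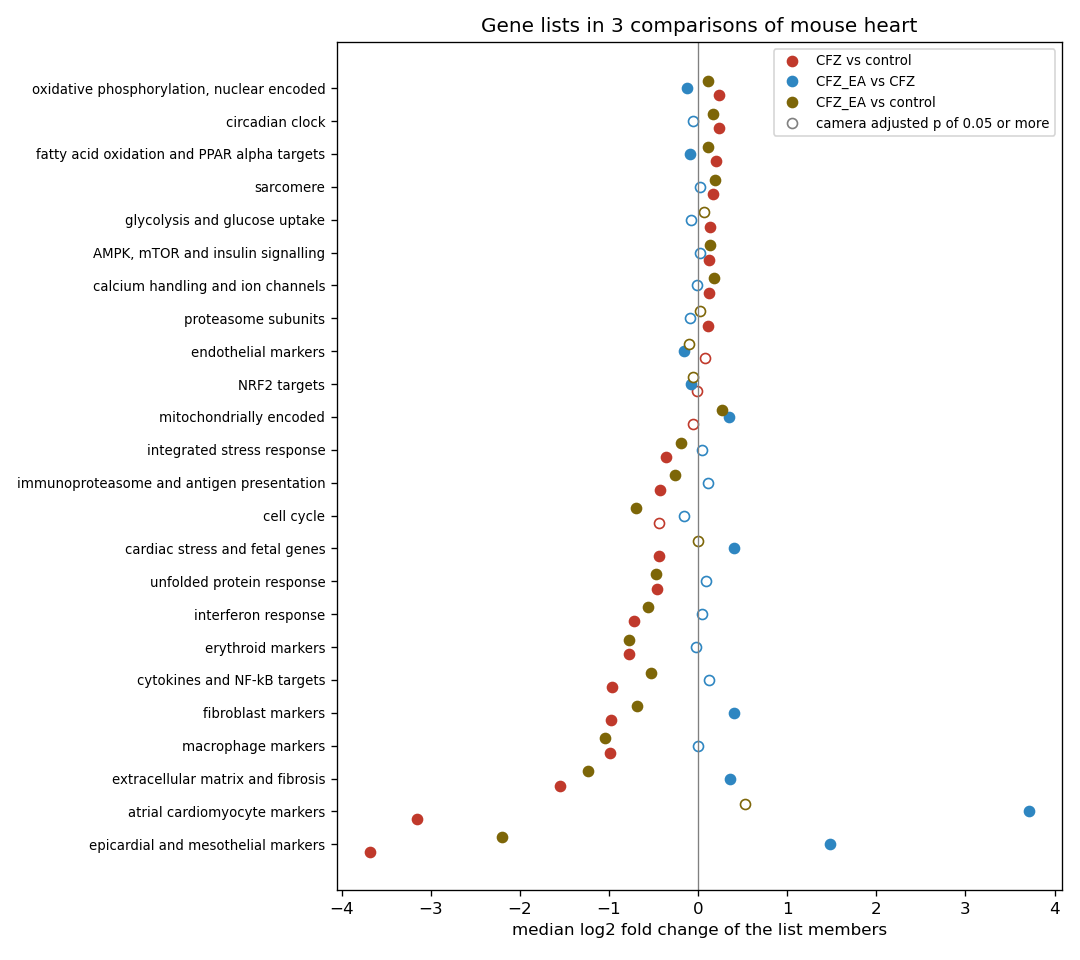
Median log2 fold change of the members of each gene list that passed in at least 1 of the 3 comparisons, with filled points for a camera adjusted p under 0.05 at the preset correlation and open points otherwise. The atrial list lies at -3.15 for CFZ against control, 3.71 for CFZ_EA against CFZ and 0.52 for CFZ_EA against control.

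The design also allowed a comparison of the carfilzomib difference with the electroacupuncture difference across genes. Over 10329 genes, Pearson's r between the log2 fold changes of CFZ against control and of CFZ_EA against CFZ was -0.63, with a covariance of -0.126. The CFZ libraries enter both with opposite sign, and 100 simulations of unchanged groups gave a median r of -0.50 and a covariance of -0.0607, so that the observed covariance differed by -0.0649. The simulated r ran from -0.53 to -0.45. Genes were drawn independently in the simulations and no library was outlying, so this range may be too narrow. An observed r outside it does not show a reversal. The log2 fold changes had opposite signs in 66.3% of the genes, against 66.7% in the simulations. With the CFZ libraries split, 1 to each side, r was -0.16 and -0.20, and 50.3% and 52.4% of the genes had opposite signs. The 2 sides then hold no library in common, so the simulated values above do not apply to the split. Unchanged groups were not simulated for it. Each side of that split holds 1 CFZ library, and genes are not independent replicates. Of 3 genes called lower in CFZ than in control and 2 called higher in CFZ_EA than in CFZ, Sept2 and Mir8114 were shared, and both had at most 1 count in each CFZ library, which enters both comparisons. At an unadjusted p under 0.05, 115 genes were lower in CFZ than in control and higher in CFZ_EA than in CFZ, and 30 went the other way. At the same threshold 214 genes were lower and 57 higher than control in both CFZ and CFZ_EA. Pearson's r between these differences from control was 0.58, against a simulated median of 0.50. With the control libraries split it was 0.052 and 0.063, and the simulated median does not apply there either. Shared CFZ or control libraries raise these counts in unchanged groups too, and the counts that unchanged groups give were not simulated.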

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

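The edgeR test itself and the DESeq2, summed-model, counts divided by 4, library totals, atrial covariate and 2-library settings were chosen after seeing the data. Where leaving out a library left a group with 1, that library was assumed to vary like the others. Gene counts without control replicate 1 rest on control replicate 2 alone, which lay apart from the other libraries. Counts of genes called (3 for CFZ against control, 2 for CFZ_EA against CFZ and 0 for CFZ_EA against control, in that order below) were 0, 0 and 0 with no filter, with overlapping models summed and with the atrial level as a covariate. They were 2, 4 and 0 in fits of the compared groups only, 1, 1 and 0 with counts divided by 4, 138, 55 and 51 with DESeq2, 37, 12 and 2 without control 2 and CFZ_EA 2, and 326, 99 and 196 at an unadjusted p under 0.05 with a 2-fold change. With 1 library left out they ran from 0 to 343, 0 to 4 and 0 to 241. Counts of passing lists (20, 10 and 18) were 0, 0 and 0 with an estimated correlation and 13, 8 and 9 without control 2 and CFZ_EA 2. For CFZ_EA against CFZ 5 passed with quantile normalisation. With 1 library left out lists ran from 14 to 22, 5 to 14 and 7 to 20. The correlation of -0.63 became -0.16 and -0.20 with the CFZ libraries split and ran from -0.74 to -0.46 with 1 library left out, for which unchanged groups were not simulated.

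With the replicate number as a block the replicate block fit called 2 (Sept2 and Mir8114, not 1500015O10Rik), 2 and 0 genes and 21, 10 and 18 lists. The labels tie the numbers to no mouse, and deviations of same-numbered libraries correlated at -0.0658, 0.0752 and -0.0547.

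Among gene values under the alternatives 4851 had the direction and side of the threshold reported, 140 passed newly, 16 no longer passed and 35 reversed. Sept2 and Mir8114 were the only called genes among these values, and all 16 lost calls were theirs. Most of the 4851 were thus uncalled genes that stayed uncalled, which says little about how firm the calls are. Among list values 850 had both, 142 no longer passed and 10 reversed. The log2 values that reversed follow, and the cause was not tested. For CFZ against control, with 1 library left out in turn, Nppb ran from -1.40 to 0.63 and Saa3 from -6.59 to 0.68. The median of the cytokines list ran from -1.37 to 0.0026. Without control replicate 2 that list is counted above as no longer passing, since a list's direction was taken from camera, where it stayed lower. Without control 2 and CFZ_EA 2 Saa3 became 0.68 and the cytokines list 0.0026. With the atrial level as a covariate Echs1 became -0.025 and Myh7 -0.43. For CFZ_EA against CFZ, with 1 library left out in turn, Nppb ran from -0.20 to 1.63, Psmb5 from -0.21 to 0.039, Vwf from -0.0086 to 0.61 and the fatty acid oxidation list from -0.21 to 0.020. Without control 2 and CFZ_EA 2 Vwf became -0.0059 and the fatty acid oxidation list 0.023. With the atrial level as a covariate mt-Nd5 became -0.0052, mt-Nd4 -0.14, mt-Nd2 -0.19, Echs1 0.089, Ppargc1a -0.10 and the mitochondrial list -0.24. For CFZ_EA against control, with 1 library left out in turn, Nupr1 ran from -1.57 to 0.16, Ndufs1 from -0.0042 to 0.59, mt-Nd5 from -0.058 to 0.88, mt-Nd1 from -0.092 to 0.92, Ccl2 from -2.55 to 0.088, Cxcl1 from -2.73 to 0.39, Nppb from -0.30 to 1.07, the oxidative phosphorylation list from -0.025 to 0.25, the mitochondrial list from -0.092 to 0.84, the fatty acid oxidation list from -0.056 to 0.35, the cytokines list from -0.90 to 0.063 and Nppa from -1.17 to 1.46. With library totals only Psmb5 became -0.032. Without control 2 and CFZ_EA 2 mt-Nd4l became -0.43, mt-Nd5 -0.28, mt-Nd1 -0.28, mt-Co3 -0.0017, Ccl2 0.26, Cxcl1 0.088, Pik3r1 -0.016, Nppa -1.56, Nppb -0.14 and the mitochondrial list -0.43, which passed as lower (camera adjusted p = 5.9e-05). With limma on unscaled FPKM Psmb5 became -0.026. With the atrial level as a covariate Nppa became -0.0063. Adjusted p of Sept2 and Mir8114 for CFZ against control were 0.0592 and 0.0592 with no filter and 0.0852 and 0.108 with the atrial covariate, and Mir8114 had 0.134 with counts divided by 4. Their fitted log2 values, which depend on the prior count, were -14.55 and -8.51 with no filter and -14.42 and -8.60 with the atrial covariate, and Mir8114 had -9.71 with counts divided by 4, against -14.58 and -8.55 in the report.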

Other observations

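Of the gene lists, 12 passed in no comparison by camera at the preset correlation. For CFZ_EA against control the heat shock and ribosomal lists lay just above the threshold (camera adjusted p = 0.05002 and 0.0560). With an estimated correlation these 2 lists had camera adjusted p = 0.661 and 0.715. Heat shock proteins had median log2 fold changes of 0.15 for CFZ against control, 0.0012 for CFZ_EA against CFZ and 0.13 for CFZ_EA against control. Ribosomal proteins had -0.034, -0.080 and -0.12, p53 targets and apoptosis genes had -0.22, 0.015 and -0.19, and ubiquitin and autophagy receptors had 0.028, -0.059 and -0.035. Muscle atrophy ubiquitin ligases had 0.14, 0.0014 and 0.15, glucocorticoid response genes -0.015, 0.11 and 0.050, immediate early genes -0.23, 0.0034 and -0.21, and cholesterol synthesis genes -0.13, 0.15 and -0.027. Nitric oxide and vascular tone genes had -0.054, -0.025 and -0.079, adrenergic and muscarinic signalling genes 0.088, 0.053 and 0.12, smooth muscle and pericyte markers -0.074, -0.027 and -0.045, and adipocyte markers 0.20, -0.24 and 0.047.

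In a contrast chosen after seeing the data, the mean of the CFZ and CFZ_EA groups was compared with control. edgeR called 0 genes higher and 2 lower, Sept2 and Mir8114, against 182 higher and 699 lower at an unadjusted p under 0.05. The CFZ libraries alone carried these 2 calls: Sept2 measured 12.2 and 15.6 FPKM in CFZ_EA against 11.5 and 16.1 FPKM in control, and Mir8114 54.8 and 43.1 against 64.0 and 47.7 FPKM. Lifr had a log2 fold change of 1.57 ± 0.14 (SE, edgeR adjusted p = 0.0888) and Manf had -1.15 ± 0.13 (edgeR adjusted p = 0.198). The unfolded protein response list had a median of -0.47 (camera adjusted p = 0.293 with an estimated correlation).

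All tests below except that of the second atrial list were chosen after the result was seen. Atrial genes were low in both CFZ libraries and high in CFZ_EA replicate 2, where Nppa measured 3882 FPKM against 646 FPKM in CFZ_EA replicate 1. A different share of atrial tissue in the pieces of heart may explain the pattern: a second list of 4 atrial genes (Sbk2, Kcnj5, Gja5, Chrm2) had median log2 differences of 0.68 between CFZ_EA and CFZ and 0.88 between CFZ_EA replicates 2 and 1. Sbk2 and Gja5 carried these medians: Kcnj5 and Chrm2 had 0.17 and 0.20 between CFZ_EA and CFZ, and Kcnj5 had -0.51 between the CFZ_EA replicates. A stress response of ventricular cells stays open, since 16 stress genes outside the atrial list had a median of 0.34 and quartiles of 0.024 and 0.66 between CFZ_EA and CFZ. An effect of electroacupuncture also stays open and cannot be told apart from the share of atrial tissue with 2 libraries, since 7 of 10 atrial genes were higher in both CFZ_EA libraries than in both CFZ libraries.

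The matrix and fibroblast lists were lower in both carfilzomib groups than in control, and their genes were high in control replicate 2. Without that library, with 1 control library left, both lists still passed for CFZ at the preset correlation. For CFZ_EA neither did, with medians of -0.14 and -0.065. Activated fibroblast genes had a median log2 difference of 3.87 between control replicates 2 and 1 (Cthrc1 measured 0.188 FPKM in control replicate 1 and 31.3 FPKM in replicate 2, and Tnc 0.102 and 9.47 FPKM), against 0.45 for resting fibroblast genes. Fibroblast markers lay 1.21 above endothelial markers in the difference between the control replicates (1.13 against -0.08). This gap cannot exclude a lower share of cardiomyocytes in control replicate 2, since more fibroblasts or macrophages need not raise endothelial markers. Between control replicates 2 and 1, macrophage markers had a median difference of 1.39, sarcomere genes -0.28 and nuclear oxidative phosphorylation genes -0.25. A lower share of cardiomyocytes stays open. Control replicate 2 may carry most of the difference, since the matrix median between CFZ and control was -0.45 without it and -1.54 with it. The matrix list still passed without it at the preset correlation, which treats its genes as nearly independent, so that pass shows little. What set control replicate 2 apart and an effect of carfilzomib on these genes were not tested separately.

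Sept2 and Mir8114 each had at most 1 count per CFZ library. Reads assigned to an overlapping model may explain these calls, since the summed models differed by -0.060 for Sept2 and 0.17 for Mir8114 between CFZ and control. The second Sept2 model, ENSMUSG00000026276, measured 1.33 and 0.261 FPKM in control, 6.42 and 5.70 FPKM in CFZ and 0.745 and 0.227 FPKM in CFZ_EA. Use of another isoform in CFZ was not tested and stays open.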
